A study of Sus scrofa with 40 samples.

How the data were processed

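RNA sequencing was analysed for 40 libraries of pig (Sus scrofa) oocytes at metaphase II, the stage at which a mature oocyte waits for fertilisation. Per the labels, the animals were a commercial hybrid of Large White, Duroc and Berkshire, and each library came from oocytes classed as mtDNA-deficient or mtDNA-normal. Libraries of pooled oocytes were made with a column extraction kit and single-primer isothermal amplification. Libraries of single oocytes were made by in-tube extraction and a kit with pig-specific primers that deplete unwanted transcripts, per the labels' protocols. All were sequenced as 100 bp paired-end reads. How the states were told apart is not stated in the labels beyond dye-test words in the titles.

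The deposited values are whole-number counts per gene, with no normalization, in 2 tables of 38795 rows, and per the submitters' processing notes FastQC, Trim Galore, TopHat2 2.0.14 and edgeR were used with genome build Sscrofa10.2. The counting program, its strand setting and the edgeR test are not given in the sources used here. Without a strand setting, reads of a gene and an overlapping antisense gene cannot be told apart, and counts of pseudogenes and near-identical copies are uncertain. Each table has 1 row that names no gene. It held 1.05% to 4.75% of the counts of a pool and 0.648% to 8.15% of those of a single oocyte, and was left out of totals and tests. Of the row names, 23893 begin with LOC and 24 are calendar dates in place of symbols. Gene names were matched through name tables of Sscrofa11.1, from which no coordinates were taken, and 23029 rows matched. Genes encoded by mtDNA and POLG2 matched no row and are not analysed here, and TFAM stayed below the count filter.

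The comparisons used 5 deficient and 6 normal pools, although the series design text gives 5 pools per group. For single oocytes, 14 deficient and 15 normal libraries were summed by state and by the first number of the title, whose meaning is not stated, into 4 deficient and 3 normal sums. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. No pair of libraries within a group agreed within sampling noise: the smallest chi-square per degree of freedom was 35.0 among pools and 4.09 among single oocytes. Columns of the single-oocyte table carry 1 of 2 dates, 17 September with 8 deficient and 9 normal oocytes and 22 September with 6 of each. The dates were used only in alternatives and observations.

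Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, after its default expression filter and TMM normalization, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each table was fitted alone. The difference of the state effect between tables was tested as an interaction term over 11 pools and 7 sums. DESeq2 1.42.0 and limma-voom (limma 3.58.1) served as alternatives. Of 24 gene lists fixed in advance, those with at least 3 tested members were compared with all other genes by limma's camera on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and again with an estimated one, and by fry. Members given as higher or lower in a list were counted by mean log2 CPM, which can differ in sign from edgeR's log2 difference. Library measures were compared by two-sided exact permutation tests, over 462 splits of the pools and 35 splits of the 7 sums. The splits of the sums were taken without regard to shared title numbers.

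The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from alternatives said to be added later. The rule took the 10 higher and 10 lower genes of largest change past the threshold with a mean CPM of at least 10, or, with fewer than 5 genes past it, the 10 genes of smallest p. It also took up to 4 members of each list past the threshold, or the 2 of smallest p with none past it, and a fixed set holding POLG, TWNK, GDF9, BMP15, ZP3 and DNMT1. Some genes that the rule took are not reported here and were left out of the search for values far from their group. Since no gene passed, genes named below did not pass the test unless said otherwise.

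The tests were tested on simulated data drawn from the real means and library sizes. For the pooled comparison (13006 simulated genes tested), edgeR recovered 12.5% of genes changed by log2 1 and 57.7% of those changed by log2 2, or 25.5% and 94.4% among genes with a CPM of at least 10, with 2 false calls. DESeq2 made 36 false calls and limma-voom 3. For the single-oocyte comparison (10981 genes), edgeR recovered 18 of 90 genes changed by log2 1 and 58.9% of those changed by log2 2, or 35.4% and 88.7% at a CPM of at least 10, with 7 false calls against 23 for DESeq2 and 2 for limma-voom. A simulated shift of the mitochondrial ribosome list was found by camera in both designs, with 0 other lists past the threshold. The simulated genes were drawn independently of each other, so this does not test camera where genes vary together.

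Title numbers shared by the 2 states in single oocytes were checked for pairing. The deviations of same-numbered sums from their group means correlated by 0.143 for number 2, 0.220 for number 3 and 0.165 for number 4, so the numbers were taken to pair the sums, and the result with the number as a block is given beside the count it changes. Alternatives covered normalization, filters, the tool, each library or sum left out in turn, blocks, letters in the titles, dates, single oocytes as samples and genes detected as a covariate. Reads without molecular identifiers are not independent molecules, so precision computed from read counts would cover counting error only. A 95% interval given for a gene list comes from the spread between sums or between pools, with limma's variance moderated over the lists.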

Results

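Gene counts were compared between mtDNA-deficient and mtDNA-normal pig oocytes at metaphase II, in pools and in single cells, to determine how the transcriptomes of the states differ. The pools comprised 5 deficient and 6 normal libraries with 14480546 to 29538982 counts each. The single oocytes comprised 14 deficient and 15 normal libraries with 706929 to 3067523 counts each. Both sets carried oocyte transcripts at high levels. GDF9, a growth factor secreted by the oocyte, stood at 1596 ± 537 CPM in pools (SD, n = 11) and 458 ± 114 CPM in single oocytes (SD, n = 29), and its partner BMP15 at 2135 ± 1175 and 788 ± 226 CPM. Of 19 markers of cumulus and granulosa cells with a count, 4 reached 10 CPM in pools and 2 in single oocytes, with medians of 0.486 and 1.02 CPM. VCAN, a matrix proteoglycan, stood at 67.3 ± 31.3 CPM in pools, and INHBA, a subunit of activin, at 49.6 ± 9.17 CPM in pools and 14.7 ± 6.68 CPM in single oocytes. CYP11A1, a steroid-producing enzyme, stood at 0.0938 ± 0.106 and 2.26 ± 2.12 CPM, and the stromal collagen gene COL1A2 at 4.99 ± 1.89 and 17.6 ± 12.01 CPM. The leading transcripts differed between the library types, which were made with different kits. DNMT1, the maintenance DNA methyltransferase, took 5.10% ± 0.996 of the counts of a pool. In single oocytes a row named LOC102158401 took 61.5% ± 6.56 of the counts and the 18S ribosomal RNA gene RN18S took 3.39% ± 0.845, so single oocytes offered fewer counts to the remaining genes.

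In pools, no gene passed the test between the states. The smallest p belonged to genes with higher values in deficient pools. MDM2, the ubiquitin ligase that restrains p53, stood at 20.1 ± 8.52 CPM in deficient pools (SD, n = 5) and 4.18 ± 2.18 CPM in normal pools (SD, n = 6), a log2 difference of 2.26 (SE 0.43, edgeR adjusted p = 0.483). SLK, a kinase, stood at 62.4 ± 23.3 and 20.7 ± 8.23 CPM, API5, an inhibitor of apoptosis, at 195 ± 51.1 and 96.9 ± 19.2 CPM, and SETD2, which trimethylates histone H3 at lysine 36, at 41.8 ± 12.5 and 17.9 ± 5.32 CPM. The others of the 10 were SHOC2 (log2 difference 1.66), N4BP1 (1.35), ZBTB18 (1.80), STRBP (0.92), PURG (12.2 ± 3.66 against 3.67 ± 1.18 CPM) and SNCAIP, which was near the floor at 0.0270 ± 0.0390 against 0.946 ± 0.414 CPM.

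edgeR called 0 genes higher and 0 lower in deficient pools among 13540 tested. At an unadjusted p under 0.05 there were 720 genes, 389 higher and 331 lower, where 677 were expected by chance. Leaving out 1 pool moved this to between 486 (without normal B2) and 1333 (without normal A3), with 1199 without deficient B2. DESeq2 called 34 higher and 24 lower, limma-voom 7 higher and 0 lower, and edgeR's exact test, added after the data were seen, 14 higher and 4 lower. MDM2, SLK and API5 passed under each of these 3 tools, with DESeq2 adjusted p of 0.000623, 0.00323 and 0.0116, and over the 22 settings besides the first fit, these 3 tools included, their adjusted p reached 0.999.

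**Figure D1:**
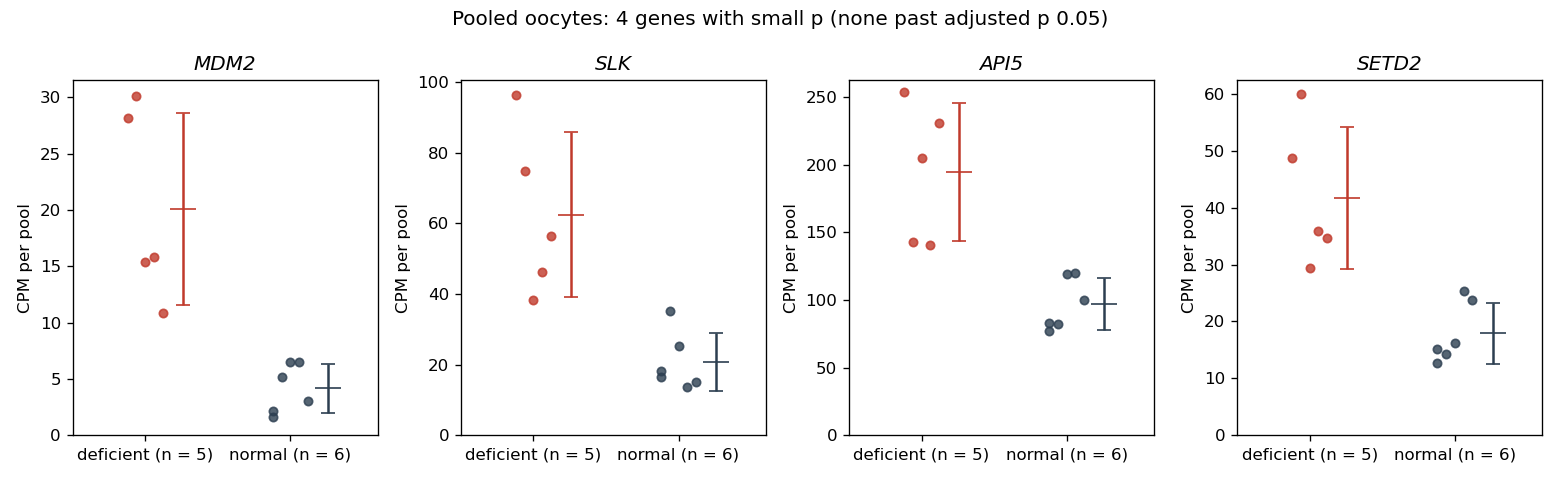
CPM of MDM2, SLK, API5 and SETD2 in each of the 5 deficient and 6 normal pools (points), with the mean and SD beside them. Deficient pools had higher means for these genes (20.1 against 4.18 CPM for MDM2), and none passed adjusted p 0.05 in edgeR.

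Among gene lists, genes of lipid synthesis and storage were lower in deficient pools by camera, 15 of 17 measured members lying lower with a median log2 difference of -0.48 (adjusted p = 0.0449). The adjusted p was 0.98 with an estimated correlation, and 0 of 23 lists passed with an estimated correlation (1 at an unadjusted p under 0.05, against 3 with the preset one) and 0 by fry. Leaving out deficient A2 or A3 or normal A2, A3, B2 or B4 ended the call (adjusted p of up to 0.292). No member passed on its own. Members are counted here by log2 CPM, and edgeR can give another sign, as for PLIN2 (-0.10 by log2 CPM, 0.03 by edgeR). AGPAT1, an enzyme of phospholipid and triglyceride synthesis, stood at 7.21 ± 2.78 CPM in deficient and 14.7 ± 3.98 CPM in normal pools, and PPARG, a nuclear receptor of lipid storage, at 96.9 ± 25.2 and 130 ± 16.4 CPM. The list's mean level followed the number of genes detected in a pool, with Pearson r = 0.917 (permutation p = 8e-05, adjusted over 2 lists 0.00016) and Spearman rho = 0.918 (permutation p = 0.00023, adjusted 0.0004) over 11 pools. This list and the mitochondrial ribosome list were those of smallest camera p among 23 lists. The permutation p-values do not cover that choice, and pools were permuted across the states. The lipid list's median level was 2.39 CPM. Members near the floor go uncounted in pools with fewer genes detected, so a positive relation is in part built in. Without the 2 pools farthest from the median number of genes r was 0.926, and within the 6 pools titled A it was 0.895. The 5 pools titled B were too few for a value. The relation was not particular to this list. With state in the model, 50 of 66 members of the cytosolic ribosome and 27 of 33 of the proteasome also rose with genes detected. For meiosis 18 of 38 rose and for mitochondrial dynamics 9 of 19. Deficient pools had 16574 ± 1666 genes detected and normal pools 17938 ± 1556 (exact permutation p = 0.197). With that number as a covariate, added after the data were seen, the adjusted p of the list by camera was 0.922. The filter of that fit kept 21 members, 12 of them lower.

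**Figure D2:**
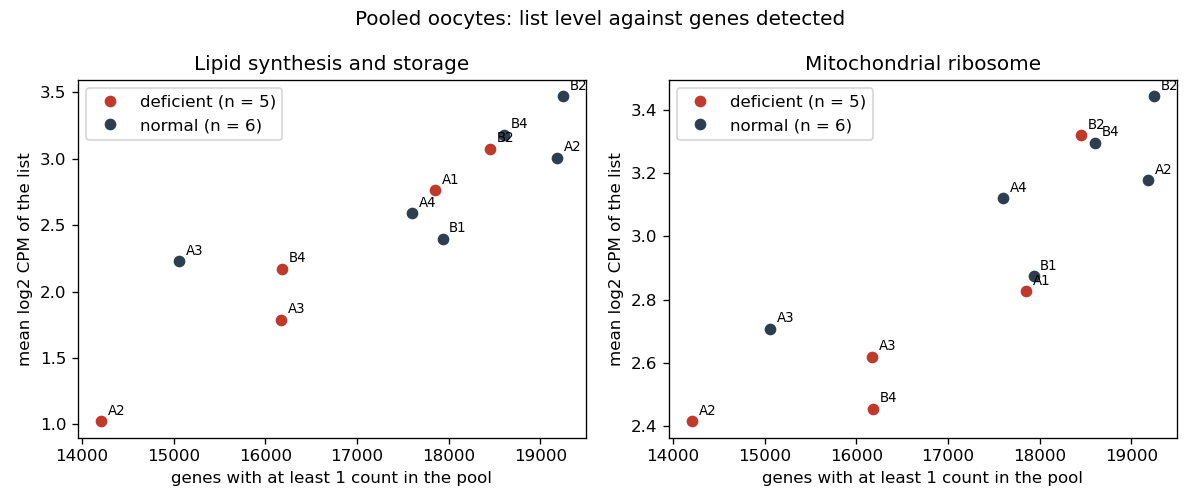
Mean log2 CPM of the lipid synthesis and storage list (left) and the mitochondrial ribosome list (right) against the number of genes with at least 1 count, for each of the 5 deficient and 6 normal pools, labelled by title name. The level follows the number of genes detected in both panels (r = 0.917 and 0.880).

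The mitochondrial ribosome list missed the threshold, with 48 of 61 members lower (adjusted p = 0.0597, and adjusted p = 0.98 with an estimated correlation), and also followed genes detected (r = 0.880, permutation p = 0.00028, rho = 0.900, permutation p = 0.0004, and r = 0.901 without the 2 farthest pools). MRPS27 and MRPS35, its members of smallest p, had edgeR log2 differences of 0.98 and 0.86, against the list's direction by log2 CPM. By log2 CPM, more members were lower in 17 of the 23 pooled lists and higher in 4. Random lists matched to the lipid list on abundance had a mean of -0.15, while edgeR's median log2 difference over all genes was -0.0019. The share of all genes lower by log2 CPM is not given here, so a majority of lower members alone shows no change of a list. Nuclear genes of respiration were lower for 15 of 24 members of complex I and 17 of 26 of complexes II to V (adjusted p = 0.927 and 0.547). Genes of mtDNA replication and transcription lay 12 higher and 12 lower (adjusted p = 0.981), and TWNK, the mitochondrial helicase, stood at 5.95 ± 2.73 and 4.93 ± 2.28 CPM. POLG, the mtDNA polymerase, was under 1 CPM in both states. In central metabolism, members were lower for 12 of 16 of glycolysis (adjusted p = 0.338), 4 of 7 of the pentose phosphate pathway (0.767), 14 of 21 of the tricarboxylic acid cycle (0.441), 11 of 18 of fatty acid oxidation (0.981) and 10 of 17 of cholesterol synthesis (0.981). DLD, a subunit of the pyruvate dehydrogenase complex, had a log2 difference of 1.18 (SE 0.35), against the direction of most members of its list.

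The remaining pooled lists were lower for 35 of 59 members of the cytosolic ribosome (adjusted p = 0.547), 22 of 33 of the proteasome (0.441), 11 of 19 of mitochondrial dynamics and mitophagy (0.981), 11 of 20 of antioxidant defence (0.845), 10 of 17 of stress response and chaperones (0.927), 20 of 38 of meiosis and metaphase II arrest (0.970), 16 of 31 of chromatin regulators (0.981), 5 of 10 of apoptosis (0.981), 8 of 18 of oocyte-specific genes (0.981) and 6 of 18 of maternal-effect genes (0.556). HSPD1, a mitochondrial chaperone, stood at 232 ± 52.2 and 147 ± 59.2 CPM, and TRAP1, a further one, at 0.960 ± 0.545 and 3.45 ± 2.44 CPM. Among oocyte-specific genes, ZP3, a protein of the egg coat, stood at 27.2 ± 11.8 and 54.4 ± 32.5 CPM, and DDX4, a germline RNA helicase, at 8.67 ± 6.04 and 3.71 ± 1.53 CPM. Among maternal-effect genes, PADI6, needed for early embryonic development, stood at 42.8 ± 19.8 and 80.2 ± 38.0 CPM, and BTG4, which promotes decay of maternal transcripts, at 4346 ± 893 and 3324 ± 779 CPM. SETDB1, a histone H3 lysine 9 methyltransferase, stood at 150 ± 18.3 and 224 ± 38.3 CPM, and SUZ12, a subunit of Polycomb repressive complex 2, at 67.7 ± 16.7 and 44.5 ± 12.8 CPM. Markers of other cells were lower for 3 of 9 members of the cumulus and granulosa list (adjusted p = 0.887), 3 of 3 of theca and stroma (0.122) and 0 of 3 of leukocytes and blood (0.469). For mtDNA replication, mitochondrial dynamics, stress response, meiosis and chromatin regulators, camera pointed up while the mean was below 0, and for oocyte-specific genes and apoptosis the median was above 0 and the mean below. Adjusted over the list alone, 0 members of any of the 23 lists passed, as over all genes.

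In single oocytes no gene passed the test either, and the values farthest apart belonged to uncharacterised loci. LOC102164107, annotated as a pseudogene, stood at 10.8 ± 9.80 CPM in the deficient sums (SD, n = 4) and 0.238 ± 0.184 CPM in the normal sums (SD, n = 3), with an edgeR adjusted p of 0.0520. It had 16 to 45 counts in 6 of 14 deficient oocytes and 0 in the other 8, while the 15 normal oocytes had at most 2. In pools it had 4 counts in 1 deficient pool and none in the other 10 pools. The long noncoding RNA LOC102167309 stood at 33.4 ± 15.8 and 104 ± 12.2 CPM, a log2 difference of -1.61 (SE 0.30, adjusted p = 0.266). A further one, LOC106506288, stood at 80.2 ± 38.5 and 147 ± 17.1 CPM (log2 difference -0.89, SE 0.27, adjusted p = 1.00). Among genes of known product, TTI2, which stabilises kinases related to phosphoinositide 3-kinase, stood at 228 ± 43.6 and 395 ± 78.7 CPM, SSFA2 at 12.7 ± 1.55 and 3.97 ± 1.43 CPM and TMEM108 at 21.8 ± 4.74 and 9.51 ± 1.76 CPM. The rest of the 10 were C5H12orf40 (log2 difference -0.92), LOC100737565 (-2.08), LOC102158335 (-2.31) and LOC100524744, which was near the floor at 2.50 ± 2.47 and 0.0333 ± 0.0576 CPM.

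edgeR called 0 genes higher and 0 lower in the deficient sums among 11964 tested, with 239 genes at an unadjusted p under 0.05. Chance would give 598 if the sums were unpaired, and this fit ignores the pairs. The 8 splits of the sums that part all 3 pairs, the real one included, gave 204 to 399. Of these, 5 reached 239, so the count is not below chance for paired sums. DESeq2 called 1 higher (LOC102164107) and 1 lower (LOC102167309), and limma-voom 0 higher and 1 lower (LOC106506288). With the title number as a block, on the 6 sums whose number both states share, edgeR called 0 higher and 2 lower among 13227 tested: LOC102167309 (log2 difference -1.42, adjusted p = 0.00338) and SIRT4, a mitochondrial sirtuin (-0.93, adjusted p = 0.0193), which over all 7 sums stood at 3541 ± 1649 and 8031 ± 4262 CPM. In the same 6 sums without the block, edgeR called 0 genes among 12059 tested (238 at an unadjusted p under 0.05). SIRT4 was outside the rule for named genes and was chosen after its values were seen. With each oocyte as a sample, LOC106506288 was lower in deficient oocytes by log2 -1.03 (adjusted p = 0.0145), where p measures the spread between oocytes. With the title number as a block as well, edgeR called 0 genes and the log2 difference of LOC106506288 was -1.01 (adjusted p = 0.0510). Without deficient sum 2, edgeR called LOC102164107 higher and LOC106506288 lower (adjusted p = 0.0157 for both). Without deficient sum 4 it called LOC102164107 higher (adjusted p = 0.0428). Without deficient sum 1, edgeR's smallest adjusted p of any gene was 0.454. LOC102164107 was tested in 20 settings besides the first fit. Its adjusted p there ranged from 1.16e-07 to 0.99985 and passed in 6. Over the 25 settings besides the first fit, those above included, the adjusted p of LOC102167309 ranged from 2.18e-07 to 1.00 and that of LOC106506288 from 4.48e-05 to 1.00. The latter stood at 74.1 ± 36.3 CPM in 14 deficient and 148 ± 48.5 CPM in 15 normal oocytes. Among oocytes of 17 September it stood at 61.0 ± 14.1 and 157 ± 53.3 CPM, and among those of 22 September at 91.6 ± 49.9 and 134 ± 40.9 CPM.

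**Figure D3:**
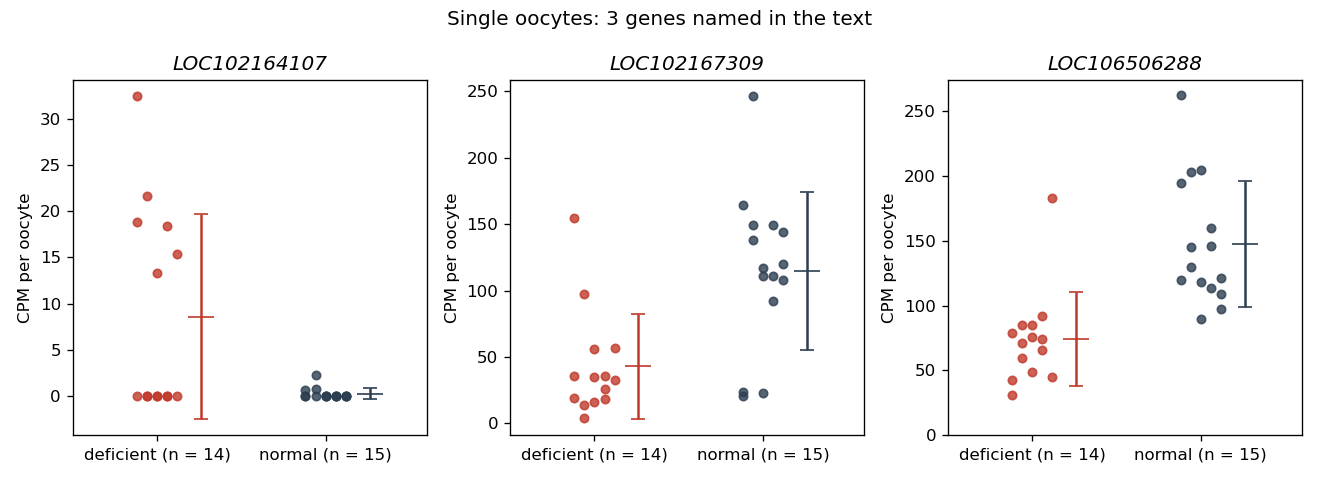
CPM of LOC102164107, LOC102167309 and LOC106506288 in each of the 14 deficient and 15 normal single oocytes (points), with the mean and SD beside them. LOC102164107 is above 13 CPM in 6 deficient oocytes, and 12 deficient oocytes lie below the lowest normal oocyte for LOC106506288 (89.9 CPM).

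No list passed camera in single oocytes: 0 of 21 with the preset correlation (0 at an unadjusted p under 0.05), 0 with an estimated correlation and 0 by fry, and adjusted p was at least 0.763. Members were lower for 12 of 16 of lipid synthesis and storage, 37 of 61 of the mitochondrial ribosome, 13 of 20 of mtDNA replication and transcription, 13 of 25 of complex I, 14 of 23 of complexes II to V, 9 of 18 of mitochondrial dynamics, 7 of 14 of glycolysis, 2 of 8 of the pentose phosphate pathway, 9 of 19 of the tricarboxylic acid cycle, 10 of 16 of fatty acid oxidation and 14 of 19 of cholesterol synthesis. They were lower for 30 of 51 of the cytosolic ribosome, 17 of 30 of the proteasome, 9 of 17 of antioxidant defence, 11 of 19 of stress response, 11 of 18 of oocyte-specific genes, 9 of 20 of maternal-effect genes, 21 of 38 of meiosis, 12 of 28 of chromatin regulators, 8 of 12 of apoptosis and 3 of 8 of the cumulus and granulosa list. More members were lower in 14 of the 21 lists and higher in 5, and the share over all genes is not given here. The theca and leukocyte lists had fewer than 3 members tested. For stress response and the proteasome camera pointed up while mean and median were below 0, and for mitochondrial dynamics, antioxidant defence and oocyte-specific genes the mean was above 0 and the median below, and for glycolysis the reverse. Adjusted over the list alone, 0 members passed. DNMT1 stood at 1467 ± 120 CPM in deficient and 1143 ± 40.02 CPM in normal sums (log2 difference 0.36, SE 0.16) and POLG at 94.4 ± 48.5 and 68.1 ± 3.99 CPM. GDF9 and BMP15 had log2 differences of -0.06 (SE 0.18) and -0.00 (SE 0.19).

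Pools and single oocytes were compared to see whether the state had the same effect in both. Of the 10 genes with the smallest p in pools, 8 were also tested in the single-oocyte sums. Their log2 differences there were 1.08 (SE 0.57) for SHOC2, 0.42 (SE 1.06) for MDM2, 0.39 (SE 0.47) for ZBTB18 and 0.11 (SE 0.67) for API5. They were 0.05 (SE 0.67) for N4BP1, -0.00 (SE 0.43) for SLK, -0.19 (SE 0.49) for STRBP and -0.45 (SE 0.43) for SETD2. Each had an unadjusted edgeR p above 0.05 there, so these signs were not settled. Of the 10 genes with the smallest p in single oocytes, LOC102164107 and LOC102167309 were not tested in pools. In pools, TTI2 (0.33, SE 0.25), SSFA2 (-0.39, SE 0.41), TMEM108 (-0.35, SE 0.24) and C5H12orf40 (0.24, SE 0.33) had the opposite sign. So did LOC100737565 (0.45, SE 0.46), LOC106506288 (0.38, SE 0.49) and LOC102158335 (0.32, SE 0.89). LOC100524744 (0.18, SE 0.30) had the same sign. The unadjusted edgeR p in pools was above 0.05 for each of these, so the signs were not settled either. edgeR's interaction term passed for 0 of 17643 genes, with 932 at an unadjusted p under 0.05. Its median SE was 1.01 on the log2 scale, so small differences between the sets could be missed. With each oocyte as a sample, a test over the spread between oocytes, it passed for 5 genes, LOC102158783, AANAT, DEGS2, LOC100624251 and LOC106504715. As no gene was called in pools, the planned share of called genes with the same sign has no value. Of 585 genes at an unadjusted p under 0.05 in pools and tested in both, 49.6% had the same sign in single oocytes, and 18 of the 35 splits of the 7 sums gave as large a share. Across 10467 genes the log2 differences correlated by r = -0.03 and rho = -0.04 (exact permutation p = 0.743 and 0.686 over splits of the sums). These splits of the sums ignore the pairs of a title number, so the share and these p-values do not allow for pairing. Genes are not independent replicates.

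Total counts, genes detected and the share of the 50 most abundant genes were tested as library measures and did not pass in either set. Pools had exact permutation p of 0.212, 0.197 and 0.472, and single oocytes 0.771, 0.343 and 0.343. Single oocytes had 12997 ± 1038 genes detected over 4 deficient means and 12408 ± 583 over 3 normal means.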

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

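The tests of mtDNA state for the lipid list and the unnamed row, of genes detected for the lipid list, of library batch and of title number 4 for the unnamed row, and of counting noise and title number for LOC102164107 were chosen after the result was seen, as were the splits for genes and lists past the threshold and for the interaction. The rest were written down before.

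The row that names no gene, which lies outside the gene comparisons, took 3.48% ± 0.719 of the counts of deficient pools and 2.16% ± 0.857 of those of normal pools, a difference of 1.32 percentage points (exact permutation p = 0.0216, 0.152 adjusted over 7 library measures). Of 3 explanations tried, 1 of them mtDNA state, fewer genes detected stays open, since the share did not pass a test against genes detected within the states (Spearman rho = -0.136, permutation p = 0.700, Pearson r = -0.193, permutation p = 0.586, and 0.145 without the 2 farthest pools). In single oocytes the difference was -0.519 percentage points (exact permutation p = 0.743), which leaves mtDNA state open. There the share differed between the dates by 2.47 percentage points (3.51% ± 1.46 in 17 oocytes and 5.97% ± 2.04 in 12, permutation p = 0.00092) but by 0.852 points within title number 4, the only number on both dates (exact permutation p = 0.407), so date cannot be told apart from title number and library batch stays open. The labels give no batch for pools beyond the letters, within which deficient means were higher (3.62% against 2.78% for A, 3.28% against 1.54% for B).

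For the lower lipid synthesis and storage list in pools, 4 explanations were tried, 3 technical and mtDNA state, 2 of them written down before the result. For a trend of fold change with abundance, 10000 abundance-matched random lists had a mean of -0.15 (95% range -0.44 to 0.16), against -0.65 for the list. Of these random lists 0.01% were as low. Their genes were drawn independently, while the list's members rose together with genes detected, so this share is too small. Abundance as a part of the shift therefore stays open. The 2 pools that stand apart also remain open, since without them the mean was -0.48 (SE 0.29, 95% interval -1.13 to 0.17) and the list no longer passed (adjusted p = 0.113). Pools with fewer genes detected remain a candidate explanation: with that number as a covariate the difference of the list's mean over 17 members went from -0.65 (SE 0.35) to -0.15 (SE 0.18). The camera call also ended with the covariate (adjusted p = 0.922). That fit kept more genes and held 21 members, 12 of them lower, so its result does not rest on the same members. The single-oocyte sums gave -0.26 (95% interval -0.75 to 0.22), which leaves mtDNA state open. Genes detected did not pass a test between the states, and a state that lowered the number of transcripts detected cannot be told apart from library complexity here.

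LOC102164107 stood highest in deficient sum 1, at 25.4 CPM against 4.44 to 7.60 CPM in the other 3 sums. A single library batch or title number as its only source was argued against, since oocytes with the transcript came from 4 title numbers and both dates. Title number 1 held deficient oocytes only, and both had the transcript (45 and 38 counts). A part of title number in the state difference therefore stays open. There were 8 deficient oocytes at 0, where Poisson draws from a common rate gave at most 1, but such draws cover read counts alone, so counting noise through loss of a few molecules before amplification stays open. Shuffling the state over oocytes gave a Fisher p as small as 0.00632 for some all-or-none gene in 0.9% of 1000 shuffles, but the gene was picked as the smallest p of all genes tested, which this share does not cover, and its adjusted p was 0.0520. A donor variant, or reads shared with the pseudogene's parent gene, may also give such a pattern and stay untested, since the labels name no animals.

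Other values stood far from the rest of their group of 4 to 6, by their gap to the nearest value. Chance flags about 1 in 20 such groups, or 9.50 of the 190 tested, and 15 were found with LOC102164107 included. In normal pools these were N4BP1 in B1 (18.2 CPM), SNCAIP in B4 (0.157 CPM), HSPD1 in A3 (265 CPM), ZP3 in B2 (116 CPM), DNMT1 in A3 (88907 CPM) and the share of the 50 most abundant genes in A3 (25.4%). In deficient pools they were PADI6 in B2 (77.9 CPM), KIF11 in A2 (72.6 CPM), SETDB1 in A2 (118 CPM) and the unnamed row in A1 (4.75%). In deficient sums they were LOC100524744 (6.17 CPM) and LOC106506288 (138 CPM) in number 2, ESRRA in number 3 (1.21 CPM) and KPNA7 in number 4 (278 CPM).

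Other splits of the samples were refitted. In pools the real split called 0 genes, a count that every split must reach (100 of 100), so it tests nothing. The highest other split called 1657, which points to a structure of the samples apart from state. For genes at an unadjusted p under 0.05, 26 of 100 splits reached the real 720 (highest other 3842), and for lists past camera 48 of 100 reached the real 1 (highest other 5), so chance cannot be excluded for either. In the single-oocyte sums the real split also called 0 genes and 0 lists, counts that 35 of 35 splits must reach. The highest other split called 15 genes, from title numbers 3 and 4 against the rest, and no split called a list. For genes at an unadjusted p under 0.05, 32 of 35 splits reached 239 (highest other 996). Among the 8 splits that part all 3 pairs of a title number, as the real one does, 0 genes were called and 204 to 399 were at an unadjusted p under 0.05, against 575 to 996 in the 3 splits that part no pair. For the interaction the real count was 0 as well, so it was fixed in advance that 50 of 50 shuffles gave as many (highest other 2).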

How the results depend on the processing

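Settings said below to be added were chosen after the data were seen. In pools, 0 genes were called under 8 of 11 alternatives and in all 11 fits that left out a pool. The exceptions were DESeq2 (34 higher, 24 lower), limma-voom (7 higher, 0 lower) and the added edgeR exact test (14 higher, 4 lower). The cause was not tested, though DESeq2 made 36 false calls in the simulation. Leaving out 1 pool moved the genes at an unadjusted p under 0.05 from 720 to between 486 (without normal B2) and 1333 (without normal A3), with 1199 without deficient B2. Whether the 4 title names shared by the states pair the pools was not settled (correlations -0.10, 0.127, 0.476 and 0.0781). With them as a replicate block on 8 pools, 0 genes were called higher and 0 lower. A3, B2 and B4 but not A2 correlated best with their own name.

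In the single-oocyte sums, 9 of 18 alternatives called 0 genes. DESeq2, no filter on low counts and the added exact test each called 1 higher and 1 lower, limma-voom 0 higher and 1 lower, and the replicate block on 6 sums 0 higher and 2 lower. Each oocyte as a sample called 1 lower, as it did with the added date covariate and among oocytes of 17 September (added), but 0 with the title number as a block and 0 among oocytes of 22 September (added). Without oocytes of fewer than 11000 genes (added) 1 was called higher. Leaving out 1 sum gave 0 to 1 higher and 0 to 1 lower: without deficient 2, 1 of each, and without deficient 4, 1 higher. The cause was not tested.

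The 1 list past camera in pools, lipid synthesis and storage, became 0 with an estimated correlation, by fry, with the added genes-detected covariate and without the 2 farthest pools (added), and 2 lists passed in a fit on the 8 pools that share a title name with the name as a block, where the block and the smaller set were not separated. Leaving out 1 pool gave 0 to 2 lists: 0 without deficient A2 or A3 or normal A2, A3, B2 or B4, and 2 without normal B1 or deficient B2. The list's adjusted p ranged from 0.00178 to 0.980 over 16 settings and its direction never turned. In single oocytes 0 lists passed under any alternative. The interaction passed for 5 genes with each oocyte as a sample and 0 with sums. The planned share of called genes with the same sign and its alternatives could not be given, since no gene was called in pools. The difference in genes detected did not pass a test with a minimum of 10 counts (-1055 in pools, exact permutation p = 0.171, and 345 in single-oocyte sums, exact permutation p = 0.514) or after thinning (-1159, exact permutation p = 0.219, and 511, exact permutation p = 0.314). No named gene reversed while called. Among uncalled named genes, 15 of 1333 pooled and 69 of 1395 single-oocyte values had another sign, and 0 of these belonged to the 10 genes of smallest p in either set. At these depths and spreads, edgeR recovered 12 of 96 simulated genes changed by log2 1 in pools and 18 of 90 in single oocytes.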

Other observations

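The test on oocytes of title number 4 and the comparison of dates were chosen after the data were seen, as were the genes named for it. Over 9 sums by state, title number and date (5 of 17 September, 4 of 22 September), edgeR with state as a covariate called 31 genes higher and 19 lower on 22 September among 11850 tested. CDC25B, the phosphatase that triggers meiotic resumption, stood at 191 ± 11.1 CPM on 22 September and 71.2 ± 14.98 CPM on 17 September (log2 difference 1.44, adjusted p = 3.54e-05). The oocyte linker histone H1FOO stood at 297 ± 40.3 and 168 ± 35.8 CPM (0.86, adjusted p = 0.0126) and the oocyte growth factor BMP15 at 1008 ± 95.2 and 656 ± 82.3 CPM (0.62, adjusted p = 0.0397). Genes lower on 22 September included LOC100525835 (log2 difference -3.17), C13H3orf30 (-5.50), the kinase ROCK1 (-1.75) and the exonuclease XRN2 (-1.04).

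Of 99 assignments of date to the 9 sums, 1, the real one, reached 50 genes, and the highest other gave 8. Sums of the same title number and date may share an origin, which such assignments can part and the real one does not. Chance is therefore not excluded. Date and title number overlap, since only number 4 holds oocytes of both dates. Within number 4, with each of 14 oocytes as a sample, edgeR called 302 genes between the dates. Of 100 assignments of date to these oocytes within the states, 1, the real one, gave as many and the highest other gave 2, which covers the spread between oocytes alone. Each date holds 1 set of oocytes per state there, so date cannot be told apart from a difference between sets. No list passed camera by date (0 of 21, smallest adjusted p 0.200 for the cytosolic ribosome). No biological explanation was tested, since the labels do not say what the dates mark.

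In pools, the split that called 1657 genes set deficient A2, A3 and B4 and normal A3 and B1 against the rest. Those 5 pools had 0.175% to 0.238% of counts in RN18S and 14207 to 17933 genes detected, and the remaining 6 had 0.427% to 1.30% and 17604 to 19245. Along the number of genes detected, with state in the model, edgeR called 1245 genes rising and 1209 falling among 16171. By camera 2 of 23 lists rose with it, lipid synthesis and storage (20 of 21 members, adjusted p = 0.0199) and cholesterol synthesis (17 of 18, adjusted p = 0.0380), and 0 passed with an estimated correlation (adjusted p = 0.527 for both). Library complexity as the common source of these lists was a hypothesis written down before that test, which leaves it open.

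A search for all-or-none genes, with at least 10 counts in 4 or more oocytes, at most 1 count in 4 or more and at most 1 oocyte between, found 4 among 29 oocytes: LOC102164107, LOC102166158 (present in 11 oocytes), LOC102162403 (5) and LOC106509759 (24). Simulated draws at the trended dispersion gave at most 2 in 100 draws, but they do not model loss of molecules before amplification, so the bound written for counting depth cannot exclude it and it stays open. Only LOC102164107 had a Fisher p under 0.05 by mtDNA state, with oocytes taken as replicates. Shuffles had a median of 0 and a 95th percentile of 1 such gene, so state as a general source of such genes stays open.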
